A study of Bacillus subtilis with 9 samples.

How the data were processed

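RNA from 3 kinds of Bacillus subtilis culture was measured on 9 Agilent arrays of a custom design (8 arrays per slide, 60-base probes), 3 per group. Per the labels' protocols, cultures of 50 ml were shaken at 170 rpm and 37 °C for 48 h in urea (3 g/l), yeast extract (0.5 g/l), peptone (1.5 g/l) and dipotassium phosphate (0.2 g/l), with glucose, glutamic acid or both. Per the labels, 500 ng of total RNA was reverse transcribed from an oligo-dT primer that carries a T7 promoter, and Cy3 was built into the copied RNA. How bacterial transcripts, most of which carry no poly(A) tail, were copied from that primer is not stated in the sources used here. The series' design text names strain 168, and the arrays' gene coordinates are those of the second RefSeq version of its chromosome. Groups and replicate numbers were taken from the source names.

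Per the file headers, the authors scanned the arrays with 1 colour and extracted the spots with Agilent Feature Extraction 11.5.1.1. The deposited processed signal is an intensity that this program had corrected for background and for spatial trends within each array, with low values replaced by surrogates and no normalization between arrays. The deposited mean signal and local background median are raw intensities, and flags for spots well above background, saturated spots and outlier spots come with them. The authors' value table holds log2 values for each array whose 75th percentile lies near 0. It correlated with the log2 mean of the processed signals per transcript at r = 0.995 to 0.998, and genes were not centred in it. Its column medians were -2.27, -2.22 and -2.52 for glucose, -0.89, -0.77 and -0.88 for glutamic acid and -0.76, -0.77 and -0.68 for both compounds, and how its probes were combined and scaled is not given in the sources used here.

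Of 15744 spots, 536 controls were left out. The levels are log2 of the processed signal minus each array's 75th percentile, taken over the 15208 other spots. Spots marked as outliers were left out, which removed 45 of 14481 probes, and spots of a probe were averaged. Probes of genes (9682 for 4105 genes) were kept if well above background on all 3 arrays of at least 1 group, and the kept probes of a gene were averaged, which left 3765 genes. Among genes called changed, kept probes disagreed in sign for 44, 48 and 12 genes in the 3 comparisons. Gene symbols were updated through a RefSeq gene table of assembly ASM904v1 for 4037 genes by locus tag, which changed 1018 names, and 68 kept the name in the files. That table gave names and neighbours only.

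Each of the 3 comparisons used limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes on all 9 arrays, two-sided, Benjamini-Hochberg over all genes tested). A gene counts as changed at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. The F test over the 3 groups used the same values and a range of group means of at least 1. Gene lists (39, written from textbook physiology) were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry. Where a gene was not well above background on any array of a group, or lay under the lowest level among probes well above background on at least 1 of its arrays, the fold is a lower bound: the bright group's mean over the mean, per array, of the higher of the gene's own level and that lowest level (on average -5.33 in glucose and -6.18 in glutamic acid). The second condition was added after the data were seen, and the choice of named genes rests on the estimates without a bound. Intergenic probes, on both strands, and tRNA probes were fitted as sets of their own in the same way. The intergenic regions used lie between 2 genes of 1 strand. Both of their probes had mean levels above -4 on the glutamic acid arrays, a limit set after the data were seen.

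The choice of design, lists, alternatives and named genes was made before the data were examined. For each comparison the rule names the 6 highest and 6 lowest genes that pass the call, have arrays apart and probes of 1 sign, the 2 largest rises and the 2 largest falls of a described list, and a fixed set of genes that includes capB, capC, capA, pgdS, ggt, rocG, gudB, gltA, glnA, ureC, aprE, tasA and spo0A. The flagellin gene hag of that set was well above background in no whole group and was not tested, and capE, not found under that name, corresponds by its place beside capA to the gene tested as edmS (ywtC in the files). Genes called dim have a brightest probe under -4 on the glutamic acid arrays (mean level), a class defined after the data were seen.

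Alternatives were quantile scaling, scaling to the median, normexp (offset 50) with either scaling, the authors' value table, other filters and probe summaries, the slide or the replicate number as a block, other variance models and calls, the 6 arrays of 2 groups alone, and each array left out. Added after the data were seen were the scan as a random block, the 5 arrays of the scan that holds both groups, and the dim genes left out. The files place the arrays on 2 slides and in 4 scans. The second slide holds 1 array, replicate 3 of both compounds, which is also alone in its scan, so the slide alternatives test that array only. The glutamic acid arrays were scanned on another day at lower detector settings, and the header of 1 of them, replicate 2, marks its grid as not good. The fits were tested on simulated data with 3765 genes, 200 of them changed by 1.5 or 3 and the genes of 2 lists shifted by 1 (log2). The noise was independent between genes, few genes changed and the groups kept a like spread, so the simulation does not test the scaling. Of changes of 1.5 (log2), 88% were found for glutamic acid against glucose, 92% for both compounds against glucose and 91% for both against glutamic acid, and of changes of 3 these shares were 100%, 99% and 99%, with 1 of 3479 unchanged genes called in each. Plots were drawn with matplotlib 3.10.9, and the files were read with pandas 2.3.3 in Python 3.11.15.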

Results

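Transcript levels were measured on 9 one-colour Agilent arrays hybridised with RNA from Bacillus subtilis, a soil bacterium that forms spores when nutrients run out. The cultures had grown for 48 h at 37 °C in a base medium of urea, yeast extract, peptone and dipotassium phosphate. They had received glucose, glutamic acid, or glucose and glutamic acid together, and each of these 3 groups has 3 arrays. The labels call the 3 arrays of a group technical replicates, so p-values measure only the spread between arrays, and the number of arrays limits the precision. The 75th percentile of the processed signal lay between 182 and 525 intensity units per array, and 77.3% to 89.2% of the spots were well above background. Per the labels the RNA was copied from an oligo-dT primer, and how transcripts without a poly(A) tail were copied is not stated, which limits what a level measures. Levels below are log2 signals relative to that percentile. The interquartile range of the log2 signals was 4.53 to 4.95 on the glucose arrays and 1.76 to 2.45 on the other 6 arrays. Gene probes exceeded intergenic probes on the strand opposite to both neighbouring genes, at the same GC content, by 1.80 to 2.23 in glucose. On the other 6 arrays that gap was 0.06 to 0.48. Rises and falls below are therefore of signal and need not all be of transcripts. Within a group, the levels of all genes correlated between arrays with r from 0.957 to 0.996, across genes, which are not independent replicates. Of 4105 genes with a probe, 3765 were tested.

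Glutamic acid was set against glucose to find which transcripts differ between the 2 inductions. Most ribosomal protein and central carbon genes were lower in glutamic acid, and most genes of late sporulation, of the prophage PBSX and of arginine synthesis were higher, although no gene list stayed called with an estimated correlation (adjusted p = 0.62). The acetoin dehydrogenase genes acoA, acoB and acoC (BSU08060, BSU08070 and BSU08080, forward strand, positions 878337 to 881580 of the strain 168 chromosome, RefSeq version 2), whose products break down the overflow product acetoin, fell, with log2 fold changes of -5.46 ± 0.10, -5.60 ± 0.13 and -5.89 ± 0.23 (± SE, 3 arrays against 3). The cell envelope stress gene liaI (BSU33130, reverse strand, 3397576 to 3397956) fell by 5.92 ± 0.11, from 6.19 ± 0.13 to 0.26 ± 0.14 (mean ± SD, n = 3). The spore crust gene cotZ (BSU11740, reverse strand, 1248754 to 1249200) was at least 24.8-fold higher, at -0.41 ± 0.14 in glutamic acid. Among genes without an established role, yhcD was at least 24.97-fold, yodN at least 23.9-fold, ybeF at least 24.2-fold and ywnC at least 19.1-fold higher, while yjfB (-5.54 ± 0.10) and ylqB (-5.46 ± 0.12) fell. The polyglutamate hydrolase homologue pghL was not well above background on the glucose arrays and was at least 11.8-fold higher in glutamic acid. The largest adjusted p among these genes was 6.5e-05, for ywnC (limma).

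By limma's moderated test with Benjamini-Hochberg adjustment and a 2-fold minimum, 2609 of the 3765 genes changed, 1501 up and 1108 down, with a median log2 fold change of 0.35 over all genes. The 3 arrays of one group all lay above the 3 of the other for 3473 genes (92.2%, where chance gives 10%). Of the genes that fell, 191 belong to the genes whose probes all averaged under -4 on the glutamic acid arrays (dim genes below), and without all such genes 2415 changed, 1498 up and 917 down. Probes of the plasmid pTA1040, near the lowest levels on all arrays, also had a lower median in glutamic acid (-8.45) than in glucose (-6.36). Falls of dim genes therefore do not by themselves show lower transcript levels. The median log2 fold change moved to -0.45 when arrays were scaled to their median and to -0.13 with quantile scaling, with splits of 1031 up and 1533 down and of 692 up and 883 down. Background correction by normexp gave 285 up and 385 down with quantile scaling, and 582 up and 902 down with the 75th percentile. The glutamic acid arrays were scanned in 2 scans that hold no other group. All 6 arrays of this comparison share 1 slide, and no scan holds both groups, so no value within a scan can be given.

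Many translation genes fell in glutamic acid. Of 53 ribosomal protein genes, 43 fell and 1 rose (median -2.95), with the largest falls in rpmA (-3.89 ± 0.27) and rplD (-3.68 ± 0.28), while rpsNB, a form of protein S14 used under zinc shortage, rose by 2.27 ± 0.10. Of 27 genes of RNA polymerase, translation factors and RNA helicases 19 fell and 2 rose (median -1.99), among them rpoB (-3.65 ± 0.28) and infC (-3.42 ± 0.21). Of 23 aminoacyl-tRNA synthetase genes 12 fell and 2 rose (median -1.22). Camera, which compares a list with all other genes, gave adjusted p = 1.9e-08, 0.00058 and 0.011 for these 3 lists at a preset correlation, and adjusted p = 0.62 for each with an estimated correlation. Quantile scaling also ended the call of the RNA polymerase list, and those of the genes rpmA, rplD, rpsNB and rpoB. In the same comparison 815 of the 942 genes brightest on the glucose arrays (25% of those tested) fell (86.5%, median -1.98). With quantile scaling the medians were -0.54 for ribosomal proteins, -0.78 for RNA polymerase and -0.93 for the synthetases. Random lists of other genes with the same glucose levels (10000 draws) had medians of -2.79, -1.94 and -0.83, in the same order. The adjusted p against these draws was 0.53, 0.93 and 0.25.

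Most genes of central carbon metabolism fell as well. In the tricarboxylic acid cycle 12 of 15 genes fell and 1 rose (median -2.72), among them pycA (-4.39 ± 0.20), whose enzyme refills the cycle, and sdhA (-4.30 ± 0.28), while citZ, for citrate synthase, fell by 2.72 ± 0.25 but stood at 0.16 with quantile scaling. In glycolysis 10 of 13 genes fell and none rose (median -1.91), among them eno (-3.23 ± 0.18) and tpiA (-2.94 ± 0.25). In gluconeogenesis 5 of 6 fell and 1 rose (median -2.02), among them gapB (-3.21 ± 0.40), which stood at 0.033 with quantile scaling, and pckA (-4.003 ± 0.31). Of 9 ATP synthase genes 8 fell (median -1.60), among them atpH (-2.56 ± 0.26) and atpC (-2.27 ± 0.30), although with quantile scaling the list's median was 0.14, atpH stood at 0.14 and atpC at 1.01. Heat shock and protein quality genes showed 16 falls and 2 rises among 21 (median -1.52), with htrA at -3.64 ± 0.25 and groEL at -3.62 ± 0.20. Camera's adjusted p was 0.00093 for the cycle, 0.0011 for glycolysis, 0.064 for gluconeogenesis, 0.011 for ATP synthase and 0.0012 for heat shock, and adjusted p = 0.62 for each with an estimated correlation. The 4 calls among these each ended under 3 alternatives, the estimated correlation and quantile scaling among them, and quantile scaling also ended the calls of eno and tpiA. With quantile scaling the medians were -1.04 for the cycle, -0.68 for glycolysis, -1.06 for gluconeogenesis and -0.83 for heat shock. Beside these groups stand the same 942 genes brightest in glucose, with their median of -1.98. Random lists with the same glucose levels had medians of -2.38 for the cycle, -1.80 for glycolysis and -1.90 for gluconeogenesis. They had -2.38 for ATP synthase and -1.60 for heat shock. The lowest adjusted p against them was 0.13, for ATP synthase, which fell less than its random lists.

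Most genes of the 3 late sporulation lists rose in glutamic acid. The SigK list of late mother cell and spore coat genes had 47 rises and 4 falls among 57 (median 2.23), the SigE list 33 rises and 3 falls among 37 (median 2.25), and the forespore list of SigF and SigG 34 rises and 3 falls among 46 (median 2.04). Examples are spoIIM (4.07 ± 0.30), which acts in engulfment, and spoVB (3.97 ± 0.22), with the coat gene cotP at least 19.4-fold higher and spoVAC, needed to load the spore with dipicolinic acid, at least 14.2-fold higher. Of 22 early sporulation genes 7 rose and 8 fell, and spo0A, the master regulator, rose by 1.66 ± 0.11, a call that ended with each other scaling. Of 33 genes of PBSX, a defective prophage, 28 rose and 2 fell (median 2.66), xkdB by 3.63 ± 0.14 and xpf by 3.54 ± 0.31. Of 12 arginine synthesis genes 9 rose (median 2.46), carA by 3.37 ± 0.22 and argD by 3.16 ± 0.24. Camera's adjusted p was 9.3e-05 for SigK, 0.00058 for SigE and for PBSX, 0.0011 for SigF and SigG, and 0.013 for arginine synthesis, and adjusted p = 0.62 for each with an estimated correlation. With quantile scaling the medians were 0.98 for SigK, 0.82 for SigE, 0.83 for SigF and SigG, 0.90 for PBSX and 0.54 for arginine synthesis, whose call ended under 3 alternatives. Random lists with the same glucose levels had medians of 1.83 for SigK, 1.90 for SigE and 1.78 for SigF and SigG. They had 2.26 for PBSX and 1.82 for arginine synthesis. The lowest adjusted p of these lists against them was 0.23, for SigK. Beside these groups stand 978 intergenic probes on the strand opposite to both neighbouring genes, with a median rise of 2.26. Of these probes 729 rose and 68 fell. Of the 767 genes dimmest in glucose (of 25%, dim genes not counted) 741 rose (96.6%, median 2.89). Both sets left out members under -4 on the glutamic acid arrays. That choice raises their shares and medians, so neither set is an unbiased measure of the rise.

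Genes for poly-gamma-glutamate, the capsule polymer of glutamic acid, changed in both directions. The synthetase genes capB and capC (BSU35900 and BSU35890, reverse strand, 3698009 to 3699654) rose by 1.01 ± 0.13 and 1.48 ± 0.16, while capA (-1.32 ± 0.12) and the depolymerase gene pgdS (-3.14 ± 0.09) fell; with quantile scaling capB stood at -0.86, and each other scaling ended the calls of capB and capC. The hydrolase homologues pghB and pghC rose by 3.04 ± 0.13 and 1.82 ± 0.13, calls that ended with quantile scaling, and ggt, for gamma-glutamyltransferase, had a value of 0.65 ± 0.09 that missed the 2-fold minimum and took the other sign with quantile scaling and with scaling to the median. Of the 8 measured genes of this list 4 rose and 2 fell (median 0.83, -0.59 with quantile scaling, camera adjusted p = 0.79). Of 21 genes of glutamate and glutamine metabolism 8 rose and 7 fell, with a median of -0.19, a mean of 0.38 and a camera adjusted p of 0.53. The glutamine uptake genes glnP and glnM were at least 18.2-fold and 11.97-fold higher, and gltA, for glutamate synthase, the aspartase gene ansB, glnA, for glutamine synthetase, and gudB, for glutamate dehydrogenase, fell, with values of -2.50 ± 0.12, -2.22 ± 0.08, -1.96 ± 0.18 and -1.69 ± 0.16, the calls of ansB, glnA and gudB ending with quantile scaling. The second glutamate dehydrogenase gene, rocG, had a value of -0.75 ± 0.10, and ureC of urease one of 0.68 ± 0.09, neither past the 2-fold minimum. With scaling to the median, and with the authors' own values, rocG passed it as a fall, and ureC took the other sign with quantile scaling and with scaling to the median.

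**Figure D1:**
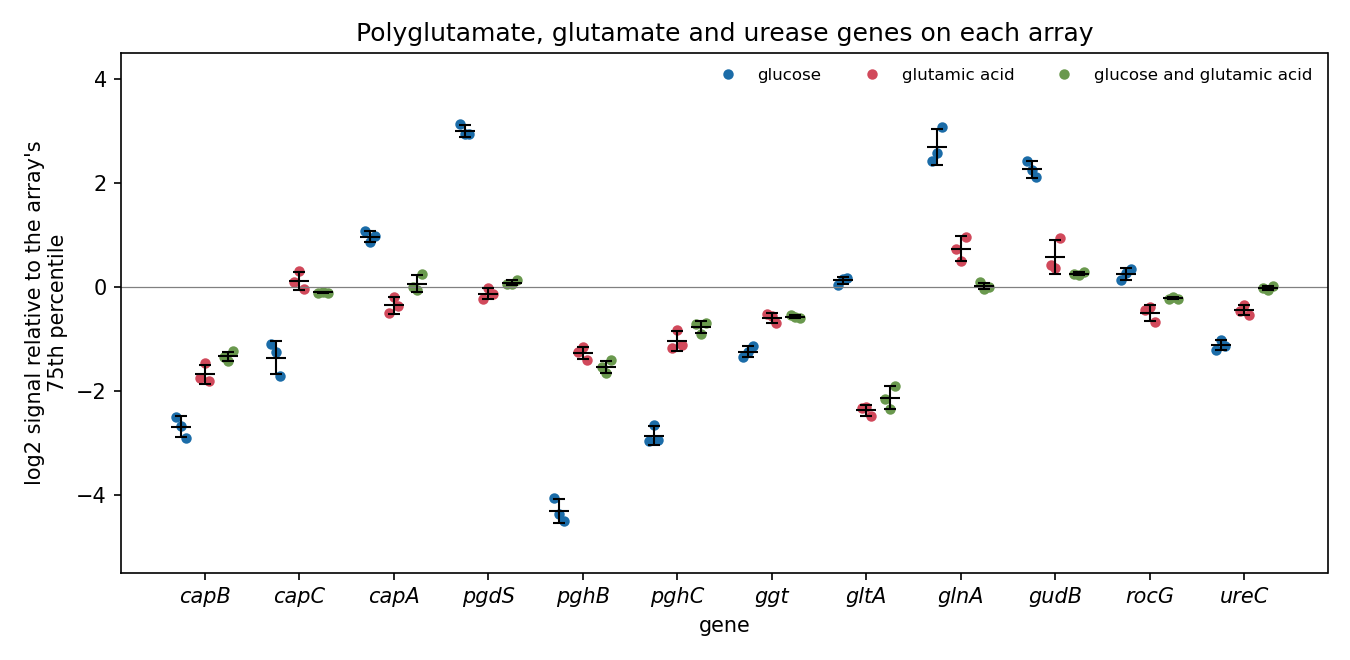
Level of 12 genes of polyglutamate, glutamate and urea use on each array (y axis, log2 signal relative to the array's 75th percentile; points, single arrays; bars, mean and SD of 3 arrays; colours, groups). The gene pgdS lay at 3.00 on the glucose arrays and at -0.13 and 0.08 in the groups with glutamic acid, and the change of capB against glucose took the other sign with quantile scaling (-0.86 and -0.74).

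Further genes that the labels' medium or the age of the culture make of interest also moved. The subtilisin gene aprE (-4.63 ± 0.24) and the matrix fibre gene tasA (-2.31 ± 0.28) fell, with a value of 0.88 for tasA under quantile scaling. The surfactin synthetase gene srfAA (-2.12 ± 0.23), acsA, for acetyl-CoA synthetase (-3.13 ± 0.23), citB, for aconitase (-2.10 ± 0.12), and the glycolytic gene gapA (-2.14 ± 0.21) fell, the calls of srfAA and gapA ending with quantile scaling. The acetolactate synthase gene alsS rose by 2.53 ± 0.09 and the competence regulator gene comK by 2.95 ± 0.15. The motor gene motA of the flagellum fell by 5.17 ± 0.17, although its list of 55 motility and chemotaxis genes had 15 rises and 16 falls. The list of 18 pyruvate dehydrogenase, acetate and acetoin genes had 11 falls and 7 rises (median -2.80, mean -1.24, camera adjusted p = 0.16). Camera called 17 of the 39 lists, 12 down and 5 up, and no list with an estimated correlation. The remaining calls were falls in branched-chain amino acid synthesis (6 of 11 genes, adjusted p = 0.014), branched-chain and fatty acid breakdown (16 of 25, 0.039), teichoic acid synthesis (14 of 20, 0.003), extracellular proteases (13 of 23, 0.020) and iron uptake (14 of 33, 0.039), each with an adjusted p = 0.62 with an estimated correlation. In the same order, these calls ended under 1, 8, 1, 4 and 8 alternatives. Dim on the glutamic acid arrays were 4 of the 20 teichoic acid, 2 of the 23 protease and 3 of the 33 iron uptake genes. In all lists of the 3 comparisons the counts adjusted over the list alone equalled those adjusted over all genes tested.

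Glucose and glutamic acid together were set against glucose to find what adding glutamic acid changes. The flotillin genes floT and floA (BSU31010 and BSU25380), whose products organise membrane domains, had the lowest values (-7.90 ± 0.45 and -7.45 ± 0.48, log2 fold change ± SE, 3 arrays against 3). Next came pdhC (-6.88 ± 0.34), for a subunit of pyruvate dehydrogenase, tasA (-6.80 ± 0.28, from 4.94 ± 0.08 to -1.87 ± 0.20, mean ± SD, n = 3), yceE (-6.77 ± 0.44) and aprE (-6.75 ± 0.24). Higher with both compounds were the arsenite efflux gene arsB (BSU25790, at least 40.9-fold), the spore coat gene cotM (at least 50.9-fold), ycgF (at least 42.5-fold), yhcD (at least 28.5-fold), yndM (at least 24.6-fold) and pghL (at least 15.7-fold). The genes arsB and ycgF are among those dim on the glutamic acid arrays. The largest adjusted p among these genes was 1.2e-06, for cotM (limma).

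In this comparison 2583 of 3765 genes changed, 1629 up and 954 down (limma), with a median of 0.62 over all genes. The arrays of the groups lay apart for 3402 genes (90.4%, where chance gives 10%). Within the scan that holds the 3 glucose arrays and 2 of the arrays with both compounds 2580 genes changed, 1614 up and 966 down. The remaining array with both compounds is alone on the second slide, and with the slide as a block 2573 genes changed. The median moved to -0.12 when arrays were scaled to their median (1214 up, 1303 down) and to -0.19 with quantile scaling (897 up, 1250 down). Normexp gave 487 up and 726 down with quantile scaling and 929 up and 838 down with the 75th percentile, and the authors' own values 1280 up and 1202 down.

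Most genes of the ribosome, of RNA polymerase and of carbon metabolism again fell. Of 53 ribosomal protein genes 43 fell and 2 rose (median -4.40), among them rpsH (-6.71 ± 0.36) and rplR (-6.67 ± 0.38), and of 27 genes of RNA polymerase and translation factors 19 fell and 3 rose (median -2.53), among them fusA, for elongation factor G (-5.73 ± 0.32), and rpoA (-5.46 ± 0.34). In the tricarboxylic acid cycle 12 of 15 fell and 1 rose (median -3.20), among them sdhA (-5.73 ± 0.28) and icd (-5.56 ± 0.27), and in glycolysis 11 of 13 fell (median -2.38), among them pgm (-5.21 ± 0.29) and tpiA (-5.07 ± 0.25). In gluconeogenesis 5 of 6 fell and 1 rose (median -2.36), among them pckA (-6.13 ± 0.31) and gapB (-5.20 ± 0.40), and of the ATP synthase genes 8 of 9 fell (median -3.12), among them atpH (-4.78 ± 0.26) and atpC (-3.89 ± 0.30). Heat shock genes had 16 falls and 2 rises among 21 (median -2.14), with htrA at -5.92 ± 0.25 and groEL at -4.94 ± 0.20. Camera's adjusted p was 3.2e-11 for ribosomal proteins, 5.7e-05 for RNA polymerase, 0.00012 for the cycle and for glycolysis, 0.035 for gluconeogenesis, 0.0055 for ATP synthase and 0.00019 for heat shock, and adjusted p = 0.64 for each with an estimated correlation. The call of gluconeogenesis ended under 5 alternatives and that of ATP synthase under 3. With quantile scaling the medians were -2.83 for ribosomal proteins, -1.66 for RNA polymerase, -2.64 for the cycle and -1.71 for glycolysis. They were -1.98 for gluconeogenesis, -1.08 for ATP synthase and -2.17 for heat shock. In the same comparison 827 of the 942 genes brightest in glucose fell (87.8%, median -2.47). Random lists with the same glucose levels had medians of -4.09 for ribosomal proteins, -2.43 for RNA polymerase, -3.12 for the cycle and -2.22 for glycolysis. They had -2.26 for gluconeogenesis, -3.04 for ATP synthase and -1.85 for heat shock. The lowest adjusted p of these lists against them was 0.47, for ribosomal proteins.

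Most genes of late sporulation, PBSX and arginine synthesis were higher with both compounds than with glucose. The SigK list had 48 rises and 2 falls among 57 (median 2.54), SigE 33 and 3 among 37 (median 2.38), SigF and SigG 34 and 2 among 46 (median 2.28), PBSX 30 rises among 33 (median 2.81) and arginine synthesis 9 rises among 12 (median 2.32). Examples are cotZ (at least 20.2-fold), spoIIM (4.22 ± 0.30), the regulator gene spoIIID (4.04 ± 0.22), the small spore protein gene sspK (3.97 ± 0.37), xkdC (4.07 ± 0.31) and carA (3.33 ± 0.22). The adjusted p by camera was 3.7e-05 for SigK, 0.0007 for SigE, 0.0013 for SigF and SigG, 0.00012 for PBSX and 0.028 for arginine synthesis, and adjusted p = 0.64 for each with an estimated correlation. With quantile scaling the medians were 1.26 for SigK, 0.93 for SigE, 0.79 for SigF and SigG, 1.11 for PBSX and 0.62 for arginine synthesis, whose call ended under 5 alternatives. Random lists with the same glucose levels had medians of 2.06 for SigK, 2.13 for SigE and 2.03 for SigF and SigG. They had 2.50 for PBSX and 2.08 for arginine synthesis. The lowest adjusted p of these lists against them was 0.24, for SigK. The opposite-strand intergenic probes rose here by a median of 2.58 (804 of 978 rose, 32 fell), and 760 of the 767 genes dimmest in glucose rose (99.1%, median 3.09). Neither set holds members under -4 on the glutamic acid arrays.

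**Figure D2:**
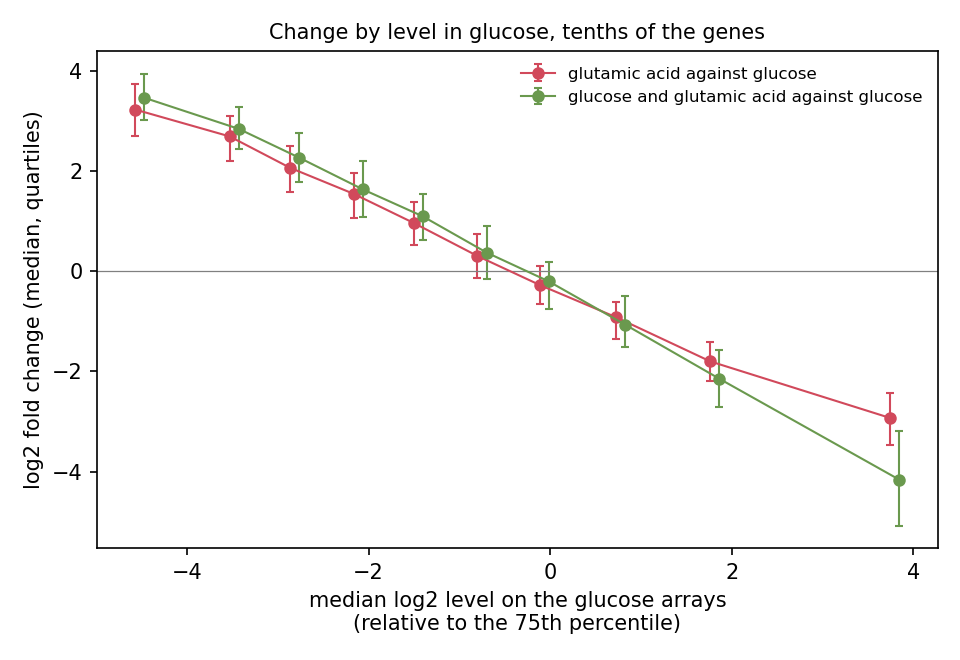
Log2 fold change against glucose (y axis; median and quartiles of the genes) by the median log2 level on the glucose arrays (x axis) for 10 equal sets of the genes that were not dim on the glutamic acid arrays. The set lowest in glucose had medians of 3.23 and 3.46 and the highest set of -2.93 and -4.16 for glutamic acid and for both compounds. The glucose level enters both axes. Leaving out the dim genes raises the medians of the sets lowest in glucose.

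Among polyglutamate genes, capB rose by 1.36 ± 0.13 and capC by 1.25 ± 0.16, with capB at -0.74 under quantile scaling and both calls ended by each other scaling. The depolymerase gene pgdS fell by 2.92 ± 0.09, pghB and pghC rose by 2.77 ± 0.13 and 2.09 ± 0.13 (calls that ended with quantile scaling), and capA (-0.91 ± 0.12) and ggt (0.67 ± 0.09, of the other sign with quantile scaling and with scaling to the median) missed the 2-fold minimum. The fall of capA passed it with scaling to the median, with the authors' own values and within the single scan. Of the 8 genes 4 rose and 1 fell (median 0.96, -0.40 with quantile scaling, camera adjusted p = 0.72). Random lists with the same glucose levels had a median of 1.09 (adjusted p = 0.89 against them). The gene glnR, for the repressor of glutamine synthetase, fell (-3.08 ± 0.31), as did glnA (-2.67 ± 0.18), gltA (-2.26 ± 0.12) and gudB (-2.01 ± 0.16, a call that ended with quantile scaling), while glnP and glnM were at least 13.2-fold and 11.7-fold higher. The list of glutamate and glutamine metabolism held 8 rises and 6 falls among 21 (median -0.31, mean 0.31, camera adjusted p = 0.46). Its random lists had a median of 0.08 (adjusted p = 0.45 against them). Of the 3 urease genes only ureC rose (1.095 ± 0.09), a call that ended with each other scaling and with the median of probes, and camera gave adjusted p = 0.42. Further values were -3.13 ± 0.23 for srfAA, -3.83 ± 0.23 for acsA, -4.72 ± 0.25 for citZ, 2.74 ± 0.09 for alsS and 2.62 ± 0.15 for comK, whose call ended with quantile scaling, and spo0A rose by 1.55 ± 0.11 but stood at -0.01 with normexp and quantile scaling. Camera called 12 lists down and 5 up. The calls not given above were falls in aminoacyl-tRNA synthetases (12 of 23, adjusted p = 0.0061), branched-chain amino acid synthesis (7 of 11, 0.0079), branched-chain and fatty acid breakdown (15 of 25, 0.012), teichoic acid synthesis (9 of 20, 0.022) and extracellular proteases (13 of 23, 0.026), each with an adjusted p = 0.64 with an estimated correlation. In the same order, these calls ended under 1, 1, 3, 1 and 3 alternatives.

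Glucose and glutamic acid together were set against glutamic acid to find what glucose changes in its presence. The matrix gene tasA (-4.49 ± 0.28), floA (-4.48 ± 0.48), the single-stranded DNA binding protein gene ssbA (BSU40900, -4.31 ± 0.61), ytxG (-4.03 ± 0.42), ydjO (-4.02 ± 0.45) and floT (-4.0008 ± 0.45) fell most when glucose was present. The 6 highest estimates belonged to genes that were dim on the glutamic acid arrays. With both compounds arsB was at least 73.5-fold, ycgF at least 89.4-fold, ynaD at least 25.4-fold, yqaQ at least 15.4-fold, ydeS at least 19.1-fold and bsuRC, for a restriction enzyme, at least 30.4-fold higher. The gene ydeS ends a run of 4 neighbouring genes that were all dim on the glutamic acid arrays. The median level of that run was -4.28 with both compounds and -5.36 in glucose. The largest adjusted p among these genes was 0.00084, for ssbA (limma).

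Of 3765 genes 576 changed, 323 up and 253 down (limma), and the median was 0.06. The arrays of the groups lay apart for 2515 genes (66.8%, where chance gives 10%). Of the 323 genes that rose, 191 were dim on the glutamic acid arrays, and without the dim genes 386 changed, 132 up and 254 down. Probes of the plasmid pTA1040, which lie near the lowest levels on all arrays, had a median of -8.45 on the glutamic acid arrays and of -5.86 on those with both compounds. The split was 314 up and 454 down with quantile scaling, 161 and 302 with normexp and quantile scaling, 93 and 182 with normexp and the 75th percentile, and 711 and 251 without the filter on dim probes. Within the slide that holds all 3 groups 561 genes changed, and with the slide as a block 556. The other slide holds only replicate 3 of both compounds, so these counts amount to leaving out that 1 array. The glutamic acid arrays share no scan with the other groups, so the scan cannot be told apart from the medium here either. The SD of the mean levels across genes was 1.84 in glutamic acid and 1.15 with both compounds. Genes of like level were not compared for these groups.

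Most ribosomal protein genes were lower with both compounds than with glutamic acid, while none of 23 aminoacyl-tRNA synthetase genes changed (median -0.10, camera adjusted p = 0.17). Of 53 ribosomal protein genes 32 fell and 1, rplK (1.90 ± 0.29), rose (median -1.38), among the falls rplR (-3.38 ± 0.38) and rpsH (-3.29 ± 0.36), and of the RNA polymerase and translation factor list 10 of 27 fell and 1 rose (median -0.53), among them fusA (-2.39 ± 0.32) and rpoA (-2.27 ± 0.34), while the cold shock gene cspB rose by 1.95 ± 0.15. Of 23 respiratory oxidase genes 8 fell (median -0.48), among them ctaD (-2.72 ± 0.32) and qcrC (-2.28 ± 0.36). In the tricarboxylic acid cycle 6 of 15 fell (median -0.58), among them citZ (-2.01 ± 0.25) and odhA (-1.99 ± 0.29), and in glycolysis 3 of 13 (median -0.47), among them pgm (-2.57 ± 0.29) and tpiA (-2.13 ± 0.25). Heat shock genes had 8 falls and 1 rise among 21 (median -0.57), with radA at -2.68 ± 0.40 and grpE at -2.30 ± 0.30. Of 22 early sporulation genes 2 fell, the phosphatase gene rapA (-3.67 ± 0.35) and phrA (-2.72 ± 0.33), whose peptide inhibits that phosphatase. Camera's adjusted p was 4.1e-11 for ribosomal proteins, 0.00074 for RNA polymerase, 0.00049 for respiratory oxidases, 0.0076 for the cycle, 0.0015 for glycolysis, 0.013 for heat shock and 0.008 for early sporulation, and adjusted p = 0.84 for each with an estimated correlation. The call of heat shock ended under 4 alternatives. Camera also called the 4 measured cannibalism toxin genes (adjusted p = 0.046, and adjusted p = 0.84 with an estimated correlation), a call that ended under 5 alternatives. All 4 were dim on the glutamic acid arrays, where levels lie at or near the background, so only bounds are given. By these bounds skfF was at least 4.25-fold and skfE at least 4.12-fold brighter, and with quantile scaling the list's median was 0.75. The bounds raise only the glutamic acid levels to a floor. Probes of pTA1040, near the lowest levels on all arrays, also rose between these groups, from -8.45 to -5.86. Differences of this size near the background therefore do not by themselves show higher expression. The opposite-strand intergenic probes had a median of 0.32, 127 of 978 rising and 1 falling.

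**Figure D3:**
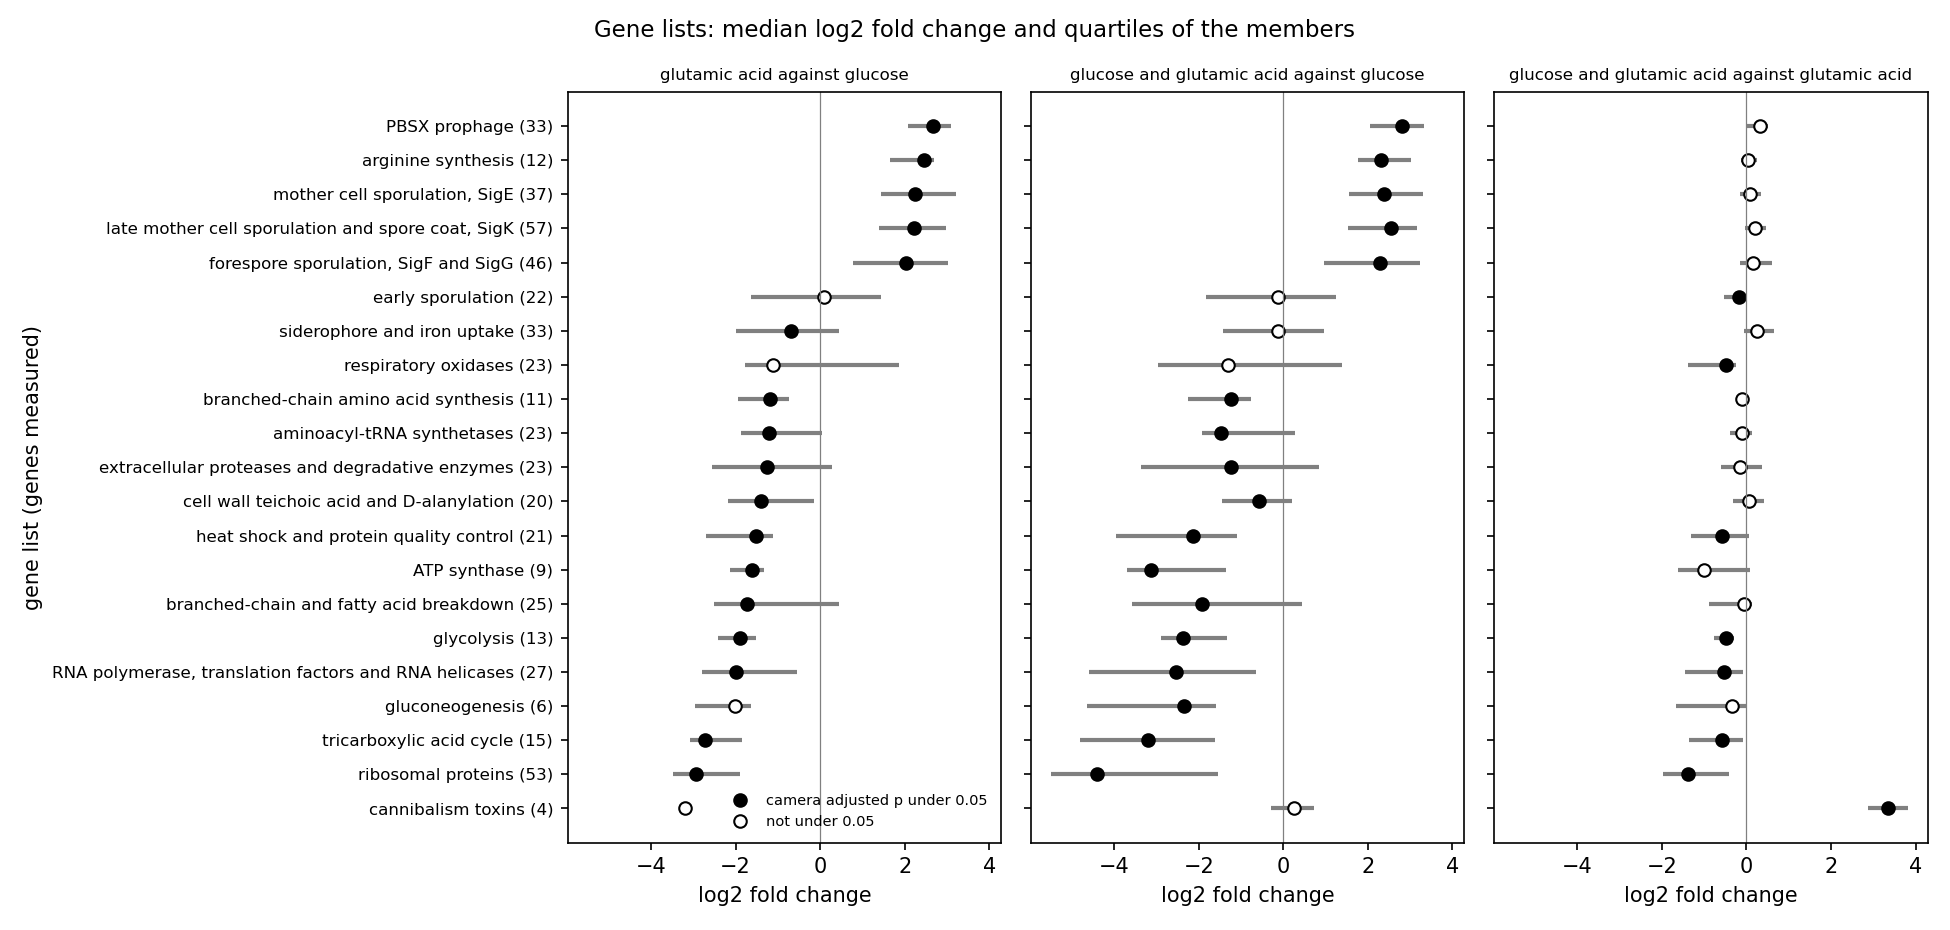
Median log2 fold change (points, x axis) and quartiles (lines) of the members of each gene list, in 3 panels for the 3 comparisons. Shown are the lists that camera called in at least 1 comparison, with the number of genes measured. Filled points have a camera adjusted p under 0.05 at the preset correlation. With an estimated correlation no list was called (lowest adjusted p 0.62, 0.64 and 0.84). Ribosomal protein genes have medians of -2.95, -4.40 and -1.38, and the late sporulation lists lie above 2 in both comparisons with glucose; with quantile scaling the ATP synthase median was 0.14 in glutamic acid against glucose, and the points of the cannibalism toxins rest on levels near the background.

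None of the 8 polyglutamate genes passed the call between the 2 media with glutamic acid, although edmS, just under the 2-fold minimum, passed it with scaling to the median. The values were 0.34 ± 0.13 for capB, -0.22 ± 0.16 for capC, 0.42 ± 0.12 for capA, 0.22 ± 0.09 for pgdS, 0.02 ± 0.09 for ggt, which took the other sign with quantile scaling, and 0.98 ± 0.20 for edmS, a small gene of the same operon, and camera gave adjusted p = 0.50 for the list (median 0.25). In glutamate and glutamine metabolism 1 of 21 genes, glnR, fell (-1.53 ± 0.31), with glnA at -0.72 ± 0.18 (past the minimum with quantile scaling), gltA at 0.25 ± 0.12 (of the other sign with quantile scaling), gudB at -0.32 ± 0.16 and rocG at 0.28 ± 0.10 (median 0.01, -0.37 with quantile scaling, camera adjusted p = 0.68), and ureC stood at 0.42 ± 0.09. The aprE and srfAA transcripts fell (-2.12 ± 0.24 and -1.01 ± 0.23, the second no longer called with scaling to the median), as did those of pckA (-2.13 ± 0.31) and gapB (-1.99 ± 0.40). Over the whole design, 2875 of 3765 genes (76.4%) differed among the 3 groups by limma's moderated F test and a 2-fold range of group means, and 3594 without that minimum.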

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

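Both tests on the plasmid probes were chosen after the result was seen. The array holds probes for 6 plasmids of the species, and a signal appeared among those of pTA1015, which enter no comparison of the report: in glutamic acid 23 of its 25 probes were brighter than the median chromosomal gene probe. All 15 coding and 8 of 10 noncoding probes lay above that median, against 0 of 32 probes of pTA1040, 4 of 32 of pTA1060, 12 of 50 of p1414, 8 of 26 of pBS608 and 5 of 17 of pLS30. The pTA1015 probes had median levels of 1.77 in glutamic acid, 1.67 with both compounds and -1.71 in glucose, where they stood near the median gene probe (-0.32 to -0.04 from it on the 3 arrays) while the other 5 plasmids had medians of -6.48 to -5.29. A plasmid related to pTA1015 in the cells, in glucose as well, is a hypothesis consistent with the 23 bright probes that stays open. A single copy in the chromosome, or hybridisation of chromosomal sequence, stays open too, since the median level of its probes, at least 1.85 above the median gene probe on each of the 6 arrays with glutamic acid, measures no copy number, and no biological explanation through the media was tested.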

How the results depend on the processing

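The scan as a random block, the 5 arrays of 1 scan and leaving out the dim genes were chosen after the data were seen. For the 4 counts, 93 of 102 alternatives stayed within 1.5 times the main count and 9 moved. Over 51 results on gene lists, 1187 of 1292 alternatives left the result called or not called as before, 89 ended a call, 14 made one and 2 reversed a called list. Over 169 values of named genes these numbers were 4094 of 4243, 103, 31 and 15. Among the 1187 and 4094 are 18 and 16 values of the other sign, all of lists and genes that were not called, except the teichoic acid list with both compounds against glucose, whose median was 0.089 with no filter on dim probes while camera's call and direction held. For every list called, the adjusted p with an estimated correlation (0.62, 0.64 and 0.84) was the highest over its alternatives.

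For glutamic acid against glucose (2609 genes), quantile scaling gave 1575, normexp with quantile scaling 670 and normexp with the 75th percentile 1484. For both compounds against glucose (2583), normexp with quantile scaling gave 1213. For both against glutamic acid (576), normexp with the 75th percentile gave 275, no filter on dim probes 962 and no minimum fold 1701, the last because the call then rests on the adjusted p alone. The genes differing among the 3 groups (2875) numbered 1400 and 1870 with normexp and quantile or 75th percentile scaling. Leaving out each array in turn gave 2566 to 2637, 2557 to 2602, 526 to 641 and 2861 to 2925 genes. With the scan as a random block the counts were 2608, 2583, 568 and 2875. The scans of the glutamic acid arrays hold no other group, so this block cannot remove a scan difference from results that use those arrays.

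Against glucose, glutamic acid gave values of the other sign with quantile scaling, and with normexp and quantile scaling, for citZ (0.16 and 0.15), gapB (0.033 and 0.064), atpH (0.14 and 0.13), atpC (1.01 and 0.98), capB (-0.86 and -0.41), tasA (0.88 and 0.94) and the ATP synthase list (0.14 and 0.13). With both compounds capB stood at -0.74 and -0.35 and, with normexp and quantile scaling, spo0A at -0.0065. Quantile scaling gives all arrays the same spread, which differed between the groups. Explanations for the related pattern, brighter dim genes and dimmer bright genes, are weighed under the other observations, and none was established.

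The replicate number as a block gave 2608, 2587, 580 and 2875 genes. Arrays of the same number in different groups correlated with r of -0.09 to 0.45, above 0.1 in 4 of 9 pairs, so the numbers were not taken to pair the arrays. Signal over background limits the dim genes, of which 197 were tested. Leaving out glutamic acid replicate 2, whose grid the header marks as not good, gave 2566 genes against glucose.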

Other observations

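The test of strand preference and the test of a raised background were chosen after the result was seen, and the split into dim genes was too. Transfer RNA probes, which no comparison of the report uses, were brighter with both compounds. Their medians per array were 4.20 to 4.26 with both compounds, 1.29 to 1.54 in glutamic acid and 1.50 to 1.68 in glucose (57 probes). Against glucose 46 of them rose and 2 fell (median 2.66), and against glutamic acid 49 rose and none fell (median 2.87), while in glutamic acid against glucose 11 rose and 17 fell (median -0.17). Only the scaling to the 75th percentile was used for these probes.

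Camera called none of 3 further lists against glucose. Of 28 competence genes 17 rose and 3 fell in glutamic acid against glucose (median 1.41, 0.43 with quantile scaling, adjusted p = 0.057), and 19 rose and 3 fell with both compounds (median 1.99, 0.41 with quantile scaling, adjusted p = 0.076). Of 22 genes of oxygen limitation and nitrate respiration 14 rose in each comparison with glucose and 3 and 5 fell (medians 1.72 and 1.81, with quantile scaling 0.56 and 0.68, adjusted p = 0.35 and 0.54). Phosphate starvation genes showed 11 rises among 18 in each, with 5 and 3 falls (medians 2.05 and 2.12, with quantile scaling 0.08 and -0.06, adjusted p = 0.39 and 0.30). Random lists with the same glucose levels had medians of 1.01 and 1.24 for competence, 1.01 and 1.21 for oxygen limitation and 1.93 and 2.21 for phosphate starvation, and the lowest adjusted p of the 3 lists against them was 0.23. Over all 39 lists the lowest adjusted p against such random lists was 0.13 for glutamic acid and 0.24 for both compounds, so no list passed.

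The first pattern weighed was that genes dim in glucose were brighter, and bright genes dimmer, on the 6 arrays with glutamic acid. Raised background is argued against as the main reason. With both compounds against glucose, probes of pTA1040 near the floor rose by a median of only 0.45, and the genes dimmest in glucose by 3.09. The latter set leaves out genes dim on the glutamic acid arrays, which raises its median. The pTA1040 probes were not chosen in that way. The medians of p1414, pLS30 and pBS608 moved further than pTA1040, from -6.48 to -5.51, -5.52 to -4.51 and -5.64 to -4.22. That of pTA1060 moved from -5.29 to -5.20, so a smaller share of raised background stays open. Sporulation as the reason for most of the rise of its genes is argued against too. The excess of its 3 lists over random lists matched on the glucose level was at most 0.48, against rises of 2.04 to 2.54. Those random lists left out only the genes of the sporulation lists, so other sporulation genes may remain in them. The SigK list lay at percentiles 98.5 and 99.4 of its random lists (adjusted p = 0.23 and 0.24). A contribution of sporulation to the rise stays open. Genomic DNA among the labelled molecules is a hypothesis that stays open. Intergenic probes lost their preference for the strand of their neighbours, with a median difference of at most -0.10 on those 6 arrays and 0.43 to 0.66 in glucose. Gene probes were brighter than opposite-strand intergenic probes of the same GC content by 1.80 to 2.23 in glucose. That gap was 0.34 to 0.48 in glutamic acid and 0.06 to 0.10 with both compounds. No prediction was made for the gap, and probes under -4 on the glutamic acid arrays were left out. The excess near the replication origin was as low as 0.046 on an array with glutamic acid (0.05 to 0.10 with SE 0.15 to 0.19 there, and 0.49 to 0.54 with both compounds) and does not decide. The scans of the glutamic acid arrays hold no other group, so for them a difference between scans cannot be told apart from the medium, and biological causes in the media stay open as well.

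The second pattern was that genes dim on the glutamic acid arrays lie together on the chromosome. Of 537 such genes, 434 lie in 32 runs of at least 4 genes, where 10000 permutations gave at most 27 genes, the longest being 88 genes from yosR to yopG, 42 from yoaE to yobJ and 33 from yqxH to yqaP. Base composition is argued against, since 8.55% of probes outside the runs with the same GC content were dim. A gene content that differs from the strain the array was designed on is a hypothesis consistent with 93.0% of 199 intergenic regions within runs being dim on both strands, against 9.11% of 2009 elsewhere, and lack of transcription stays open as well, since 81.0% of 63 genes outside the runs as dim in glucose were dim too. Some of those genes may also be absent from the strain.

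Other splits of the arrays were counted for each result. Each comparison of 3 arrays with 3 allows 10 splits, too few for a share under 0.05, and the real split gave 2609, 2583 and 576 genes while the highest of the others gave 0 in each, so that only 1 split reached the real count. For the 3 groups, 1 of 100 splits drawn from 280, the real one, gave as many as 2875 genes, and the highest other gave 2553. Chance can be excluded there for the spread between arrays only, since the arrays are labelled technical replicates and chance differences between cultures were not tested. The 5 other splits that kept the glucose arrays together gave 2528 to 2553, and all others at most 177, which shows that the glucose arrays stand apart from the remaining 6.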
